A study of Homo sapiens with 4 samples.

How the data were processed

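RNA was measured by sequencing in 4 libraries of HLE cells, an established human hepatocellular carcinoma line with few hepatocyte features. Per the labels, 2 libraries came from cells stably carrying an empty vector and 2 from cells stably expressing CYR61, a secreted matrix-associated protein of the CCN family whose current symbol is CCN1. The series description, not the sample titles, calls the 2 replicates per group independent cultures of the total population of each stable line. On that reading, p-values measure the spread between cultures of each cell population. They do not measure the spread between separately made stable populations, and whether either population was made more than once is not given in the sources used here.

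The authors deposited 1 table of estimated counts per library, with 20286 Ensembl gene identifiers each. Between 11.2% and 12% of the values per library were not whole numbers, so the deposited values were treated as estimated counts and not as raw read counts. Per the submitters' processing notes, the genome build was hg38 and the tools were TopHat2 2.1.1, Cufflinks 2.2.1 and Cuffdiff 1.3.0. The program that made the estimated counts, the annotation release and the strandedness of the libraries are not given in the sources used here. Without strand, reads of overlapping or antisense genes cannot be told apart. Division of reads between overlapping gene models or near-identical copies affects single genes. Overlaps of exons were looked for on the same strand only, so overlaps with antisense genes were not searched. For genes named by the rule below with an overlap or near-identical copy found, the gene is called uncertain or the locus sum is given.

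The estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with its default settings, which left 12698 genes to test. The remaining 7588 were not tested, and 4187 of these had 0 counts in the 4 libraries. Libraries were scaled by TMM, and CPM values are from edgeR's cpm function with the TMM-scaled library sizes. The comparison was fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) on group alone, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are CYR61-expressing minus vector, and each standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic. Values per group are means with the sample standard deviation (SD) of 2 cultures. A called gene is one with an edgeR adjusted p below 0.05. Where a group had 0 counts in both libraries, a lower bound on the fold was computed from a floor of 3 counts per library, and it covers counting error only.

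Symbols came from a table of gene names that held 20228 of the 20286 identifiers. Positions came from GENCODE release 29 on GRCh38, the assembly that hg38 names, which held 20212 of them. GC content came from the transcripts of the same release and was known for 12668 of the 12698 tested genes.

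The test, the gene lists, the rule for named genes and the alternatives listed as planned were fixed before the data were examined. The named genes were CYR61, then the 10 higher and the 10 lower called genes with the largest change, a mean of at least 1 CPM and no overlap between groups, leaving out clone-based, antisense, small RNA and pseudogene symbols. Up to 4 called members of smallest adjusted p per gene list were added, or 1 member of smallest p where none was called. The genes of the TGF-beta and YAP pathways in the series title and the gene with most reads were added whatever their test. Members of a list named beyond these were chosen after their values were seen. There were 26 lists of pathway genes, markers of other cell types and RNA quality genes, with CYR61 left out of each. Of these, 25 had at least 5 tested members. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 25 lists. Camera with a correlation estimated from the data and fry were run beside it. With 4 libraries an estimated correlation is itself uncertain, and camera then also uses the few residual degrees of freedom.

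The alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, upper quartile scaling, library size alone, no filter, a filter of 5 CPM in 2 libraries, the replicate number as a block, each library left out in turn, CYR61 left out of the library sizes, a minimum fold of 1.5 and a prior count of 2. Removal of the per-library trend on GC content (a natural spline with 5 degrees of freedom), alone and with the replicate block, and a block with crossed numbers were added after the data were seen.

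Scripts were tested on simulated counts for this comparison with 200 changed genes among 12595 tested. The edgeR test recovered 30% of the genes changed 1.5-fold, 82% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, with 13 false calls. With a further GC trend simulated and left in, it recovered 6% at 1.5-fold, 74% at 2-fold and 100% at 4-fold or 8-fold. There were 0 false calls among 12583 genes. The simulated dispersions came from the real libraries and already held the spread of their GC trend. That run therefore has more spread than the reported fit. With the further trend removed, the edgeR test recovered 32%, 88%, 100% and 100%, with 7 false calls. Of 200 simulated unchanged gene sets, 2 had a camera p below 0.05. The self-test simulated independent genes, so it says nothing of sets whose genes vary together. Figures were drawn with matplotlib 3.10.9.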

Results

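The transcriptome of HLE cells, a human hepatocellular carcinoma line, was profiled in 2 cultures carrying an empty vector and 2 cultures stably expressing CYR61. The libraries held 19118548 (vector 1), 21588822 (vector 2), 21388465 (CYR61 1) and 16186988 (CYR61 2) estimated counts. Between 14573 and 15068 genes had a count in each. The 10 most abundant genes took 6.8% to 7.2% of the counts. Chi-square per degree of freedom over genes was 13.9 between the vector libraries and 15.3 between the CYR61 libraries. It was 39 to 67.1 for pairs of libraries from different groups. These values include CYR61 itself, so part of that gap comes from the introduced gene. Part of the spread within groups followed GC content. Over 10364 genes of at least 5 CPM, Spearman's rho across genes, which are not independent replicates, was -0.73 for vector 2 minus vector 1 and -0.78 for CYR61 1 minus CYR61 2. It was -0.17 for the log2 fold change between groups.

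The comparison asks which transcripts differ when CYR61 is stably expressed. CYR61 (CCN1, ENSG00000142871, hg38 chromosome 1, 85580761 to 85583962, plus strand) was measured first, as a check of the labels. It rose from 220 ± 2.28 CPM in vector cells to 8360 ± 374 CPM in CYR61-expressing cells (mean ± SD, n = 2 each), a log2 fold change of 5.25 (SE 0.13, edgeR adjusted p = 1.33e-08) or 38-fold. The estimated counts were 4172 and 4818 in the vector libraries and 173927 and 137582 in the CYR61 libraries. CYR61 took 0.0218% and 0.0223% of the counts in the vector libraries and 0.813% and 0.85% in the CYR61 libraries. Reads of the introduced and the endogenous gene cannot be distinguished in gene counts.

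Beyond CYR61, more genes fell than rose. Of 12698 genes tested, 811 were called, 232 higher (28.6%) and 579 lower (71.4%) in CYR61-expressing cells. Of these, 25 were at least 2-fold higher and 237 at least 2-fold lower. The median log2 fold change of the tested genes was -0.006. The balance of directions depended on the processing. With the GC trend removed from each library, 3621 genes were called, 57.8% higher and 42.2% lower, and these included the 811 with the same sign. DESeq2 called 937 genes, 40.2% higher and 59.8% lower. Leaving out vector 1 gave 481 calls and leaving out CYR61 2 gave 1331.

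**Figure D1:**
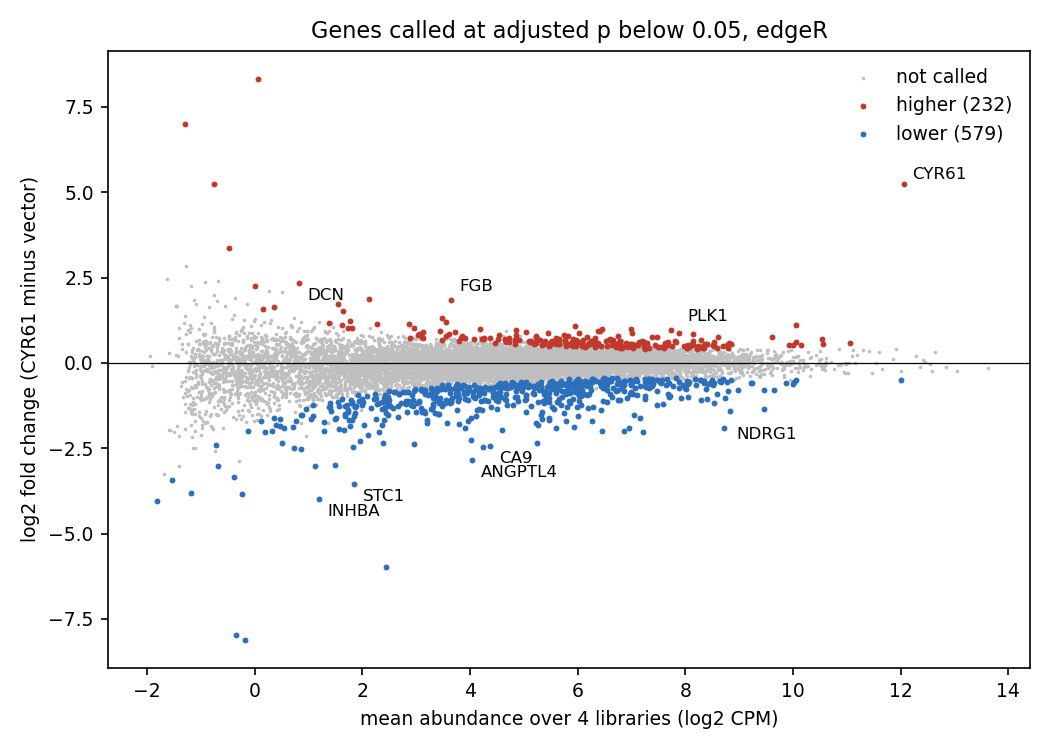
Log2 fold change (CYR61 minus vector) of each tested gene against its mean abundance over the 4 libraries in log2 CPM, with called genes in red (232 higher) or blue (579 lower) and the others in grey. CYR61 lies at 5.25, and called genes lie below 0 more often than above it.

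The genes with the largest falls included 4 that encode secreted factors, INHBA, STC1, INHBE and ANGPTL4. INHBA, the beta A subunit of activin (ENSG00000122641, chromosome 7, 41667168 to 41705834), fell 16-fold, from 4.35 ± 0.902 to 0.249 ± 0.175 CPM (log2 fold change -4.00, SE 0.45, edgeR adjusted p = 0.000877). STC1, encoding the glycoprotein hormone stanniocalcin, fell 11.8-fold from 6.66 ± 0.123 to 0.545 ± 0.15 CPM (edgeR adjusted p = 0.000191). INHBE, the inhibin beta E subunit, fell 7.88-fold from 5.03 ± 0.39 to 0.607 ± 0.326 CPM. ANGPTL4, a secreted inhibitor of lipoprotein lipase, fell 7.2-fold from 29 ± 4.98 to 4 ± 0.6 CPM. KLHDC7B fell 8.08-fold, the sodium channel gene SCN4A 5.58-fold, the NKG2D ligand gene ULBP1 5.53-fold and the glutathione-degrading enzyme gene CHAC1 5.51-fold. Counts of several of these genes in the CYR61 libraries were low, at 8 and 2 for INHBA and 14 and 7 for STC1. The list of the 10 largest falls was completed by FAM220A and MYZAP, whose loci hold a second gene model. FAM220A had a log2 fold change of -5.98 (SE 0.43, edgeR adjusted p = 0.000103). SAGSIN1, which shares its span, was higher by 1.20, and the summed CPM of both was 17.6 and 17.8 in vector and 16 and 17.1 in CYR61 libraries. The fall of FAM220A is therefore uncertain. MYZAP had a log2 fold change of -2.52 (SE 0.65, edgeR adjusted p = 0.0483) and overlaps GCOM1, with a log2 change of the sum of -1.70. MYZAP had 0 counts in CYR61 2 and was not called by DESeq2 (adjusted p = 0.575) or with library size alone (edgeR adjusted p = 0.0876).

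The largest rises after CYR61 were in genes of low abundance. The fibrinogen chain genes FGB and FGA, normally expressed in hepatocytes, rose 3.6-fold (from 5.43 ± 0.574 to 19.5 ± 1.89 CPM, edgeR adjusted p = 0.000436) and 3.67-fold (from 1.87 ± 0.14 to 6.81 ± 1.3 CPM, edgeR adjusted p = 0.00259). DCN, encoding the matrix proteoglycan decorin, rose 5.07-fold from 0.59 ± 0.0661 to 2.97 ± 1 CPM (edgeR adjusted p = 0.00746). VAV3, a guanine nucleotide exchange factor gene, had a log2 fold change of 1.51, the potassium channel gene KCND3 1.57, ACSM3 1.65 and CNTNAP3B 2.26. CNTNAP3B has near-identical paralogs and is uncertain. Each of these 4 calls was lost when some library was left out. Without vector 1 the edgeR adjusted p was 0.091 for VAV3, 0.175 for KCND3 and 0.0814 for ACSM3. Without vector 2 it was 0.202 for KCND3, 0.167 for ACSM3 and 0.122 for CNTNAP3B. Without CYR61 1 it was 0.154 for KCND3 and 0.146 for CNTNAP3B, and without CYR61 2 it was 0.0583 for ACSM3. KCND3 was also not called with library size alone (0.0562). A pair of identifiers without a symbol completed the list. ENSG00000285901, which overlaps TIGAR and CCND2, had 0 counts in both vector libraries and 30.4 and 43.7 in the CYR61 libraries, at least 14.1-fold higher. It is uncertain, since reads may be divided between the models. ENSG00000263020, which overlaps CSNK2B and LY6G5B, had a log2 fold change of 1.72 and is uncertain for the same reason.

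Some genes induced by low oxygen and some genes of glycolysis were lower in CYR61-expressing cells. Of 27 tested members of the joint list, 13 fell and 0 rose (17 and 0 adjusted over the list alone), with a median log2 fold change of -0.58. Besides ANGPTL4, CA9, a cell-surface carbonic anhydrase, fell from 35.2 ± 4.49 to 6.47 ± 0.597 CPM (log2 fold change -2.44, SE 0.18, edgeR adjusted p = 0.000103). The glucose transporter gene SLC2A3 fell from 26.9 ± 2.94 to 5.6 ± 0.0374 CPM (log2 fold change -2.26), and NDRG1 from 669 ± 82.7 to 177 ± 13.6 CPM (log2 fold change -1.92). ALDOC, ENO2, VEGFA, PFKFB4, EGLN3, ADM, HK2, BNIP3 and ANKRD37 also fell. The other 14 members were not called, such as ENO1 (-0.02), LDHA (-0.01), ALDOA (0.02), PGK1 (-0.37), KDM3A (-0.01) and SLC2A1 (-0.49). By camera the adjusted p was 2.08e-08 with the preset correlation and adjusted p = 0.413 with an estimated correlation.

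In the joint list of unfolded protein and amino acid response genes, 12 of 23 members were lower and 0 higher (13 and 0 adjusted over the list alone), with a median log2 fold change of -0.56. ASNS, asparagine synthetase, fell from 185 ± 15.3 to 46.2 ± 4.58 CPM (log2 fold change -2.00, SE 0.13, edgeR adjusted p = 7.07e-05). PHGDH, which opens serine synthesis, fell from 658 ± 35.1 to 248 ± 26.2 CPM (log2 fold change -1.40), and the pseudokinase gene TRIB3 from 215 ± 19.1 to 70.1 ± 8.73 CPM (log2 fold change -1.62). CHAC1, PSAT1, SESN2, ATF3, ATF4, DDIT3, VLDLR, XBP1 and HERPUD1 were the other called members. The other 11 were not called, such as the endoplasmic reticulum chaperone genes HSPA5 (-0.15), HSP90B1 (0.10), PDIA4 (0.01) and CALR (-0.09). For this list the camera adjusted p was 9.56e-07, and adjusted p = 0.326 with an estimated correlation.

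Some immediate-early genes and feedback regulators of EGFR and MAPK signalling fell as well. Of 22 members, 11 fell and 0 rose (14 and 0 adjusted over the list alone), with a median log2 fold change of -0.68. PHLDA1 fell from 67.3 ± 3.74 to 21 ± 2.51 CPM (log2 fold change -1.68, SE 0.14, edgeR adjusted p = 0.000191). The phosphatase genes DUSP4 (log2 fold change -1.44) and DUSP5 (-1.27) and the transcription factor gene ETV5 (-1.60) fell. ETV5 overlaps DGKG, and the sum over the locus changed by -1.60. EGFR itself, EGR1, FOS, FOSL1, SPRY4, EPHA2 and DUSP6 were the other called members. The other 11 were not called, such as SPRY2 (-0.72), SPRY1 (0.31), SPRED1 (-0.23), SPRED2 (-0.17) and ETV4 (-0.16). Over the 22 members, 19 log2 fold changes were below 0 and 3 above. The camera adjusted p was 6.64e-08, and adjusted p = 0.326 with an estimated correlation.

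The series title names TGF-beta and YAP signalling, and the targets of each pathway were tested as a list; the lists were not compared with each other. Of 22 TGF-beta/SMAD target genes, 8 fell and 0 rose (10 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -0.24. With the GC trend removed, 10 of these genes were lower and 3 higher. BHLHE40, a transcription repressor gene, fell from 252 ± 12.5 to 107 ± 11.4 CPM (log2 fold change -1.24, SE 0.12, edgeR adjusted p = 0.000435). The transcription factor genes JUNB (-0.97) and KLF10 (-0.84) fell, as did TSC22D1, LTBP2, PMEPA1 and ID1. The other 14 members were not called, such as SMAD7 (-0.21), SKIL (-0.22), TGFBI (-0.18), THBS1 (0.05) and BAMBI (0.53). By camera the adjusted p was 0.000748, and adjusted p = 0.422 with an estimated correlation; the fry adjusted p was 0.0511. Of 24 YAP/TAZ target genes, 6 fell and 2 rose (7 and 2 adjusted over the list alone), with a median of -0.12, and the list was not called (camera adjusted p = 0.221, and adjusted p = 0.627 with an estimated correlation). IGFBP3 fell by 1.10 on the log2 scale, GADD45A by 1.00 and NT5E by 0.65, while FJX1 rose by 0.72. NT5E was not called without vector 1 (edgeR adjusted p = 0.107) or without vector 2 (0.0692). FJX1 was not called without vector 1 (0.0883). With 1 library left out, 2 YAP/TAZ target genes were lower without vector 1, 2 without vector 2, 3 without CYR61 1 and 6 without CYR61 2. Higher members numbered 0 without vector 1 and 1 without any other library. With the GC trend removed, 6 were higher and 8 lower.

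The pathway components themselves were not called in the planned fit. The log2 fold change was -0.24 for YAP1 (169 ± 20.6 and 143 ± 20.7 CPM, edgeR adjusted p = 0.331), 0.06 for WWTR1, which encodes TAZ, -0.16 for TEAD1 and 0.23 for TEAD4. It was 0.05 for TGFB1 (197 ± 16.7 and 205 ± 14.1 CPM, edgeR adjusted p = 0.837), -0.13 for TGFB2, -0.10 for TGFBR1 and -0.27 for TGFBR2. It was -0.35 for SMAD2 (edgeR adjusted p = 0.12), -0.20 for SMAD3 and -0.06 for SMAD4. SMAD4 overlaps ENSG00000267699, so its value is uncertain. CCN2, another CCN family gene and a member of the YAP/TAZ target list, was at 55.7 ± 2.99 and 65.4 ± 12.4 CPM (log2 fold change 0.23, edgeR adjusted p = 0.402). With the GC trend removed, SMAD2 (-0.38, edgeR adjusted p = 0.0032), TEAD4 (0.36, 0.00465), YAP1 (-0.25, 0.0289), TGFB1 (0.20, 0.0364) and TGFBR2 (-0.25, 0.0428) were called. The sign of TGFB1 turned without vector 2 (-0.03) or CYR61 2 (-0.02), and that of TGFBR1 without vector 2 (0.03).

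Some proliferation genes were higher. Of 30 proliferation genes, 7 rose and 0 fell (13 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.32. The mitotic kinase gene PLK1 rose from 167 ± 12.2 to 305 ± 15.4 CPM (log2 fold change 0.87, SE 0.11, edgeR adjusted p = 0.00195), and the cyclin gene CCNB1 from 133 ± 0.514 to 224 ± 17.9 CPM (0.75). AURKA (0.68), KIF20A (0.65), CDC20, CCNA2 and MKI67 also rose. The other 23 members were not called, such as BUB1 (0.41), CDK1 (0.42), MCM5 (-0.30), PCNA (-0.01) and E2F1 (-0.41). For this list the camera adjusted p was 5.48e-05, and adjusted p = 0.326 with an estimated correlation; the fry adjusted p was 0.0661. The number of higher members was 3 without vector 1 and 13 without CYR61 2. With the GC trend removed, 19 were higher and 2 lower. AURKA was not called without vector 1 (edgeR adjusted p = 0.0929), nor KIF20A without vector 2 (0.0586).

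Of 20 p53 target genes, 6 fell and 0 rose (8 and 0 adjusted over the list alone), with a median log2 fold change of -0.14. GDF15, a stress-induced cytokine gene, fell from 63.2 ± 9.42 to 12.5 ± 3.3 CPM (log2 fold change -2.35, edgeR adjusted p = 0.000185), and CDKN1A, the p21 cell cycle inhibitor gene, from 84.4 ± 2.81 to 26 ± 0.0802 CPM (-1.70). SESN2 (-1.15), which is also in the amino acid response list, BBC3 (-1.09), DDB2 and PLK3 were lower. The other 14 members were not called, such as MDM2 (-0.03), BAX (-0.03), XPC (-0.45) and FAS (0.29). Over the 20 members, 16 log2 fold changes were below 0 and 4 above. The camera adjusted p was 0.0119, and adjusted p = 0.422 with an estimated correlation. Of 14 NF-kappaB and secretory inflammatory genes, 2 fell, IER3 (-1.64) and the cytokine gene IL11 (-1.53), with 10 lower adjusted over the list alone and a median of -0.42 (camera adjusted p = 4.7e-05, and adjusted p = 0.326 with an estimated correlation). IL11 was not called without vector 1 (edgeR adjusted p = 0.275), by DESeq2 (adjusted p = 0.0912) or by limma-voom (adjusted p = 0.0502). Lower list members numbered 1 without vector 1, 4 without vector 2, 3 without CYR61 1 and 4 without CYR61 2.

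**Figure D2:**
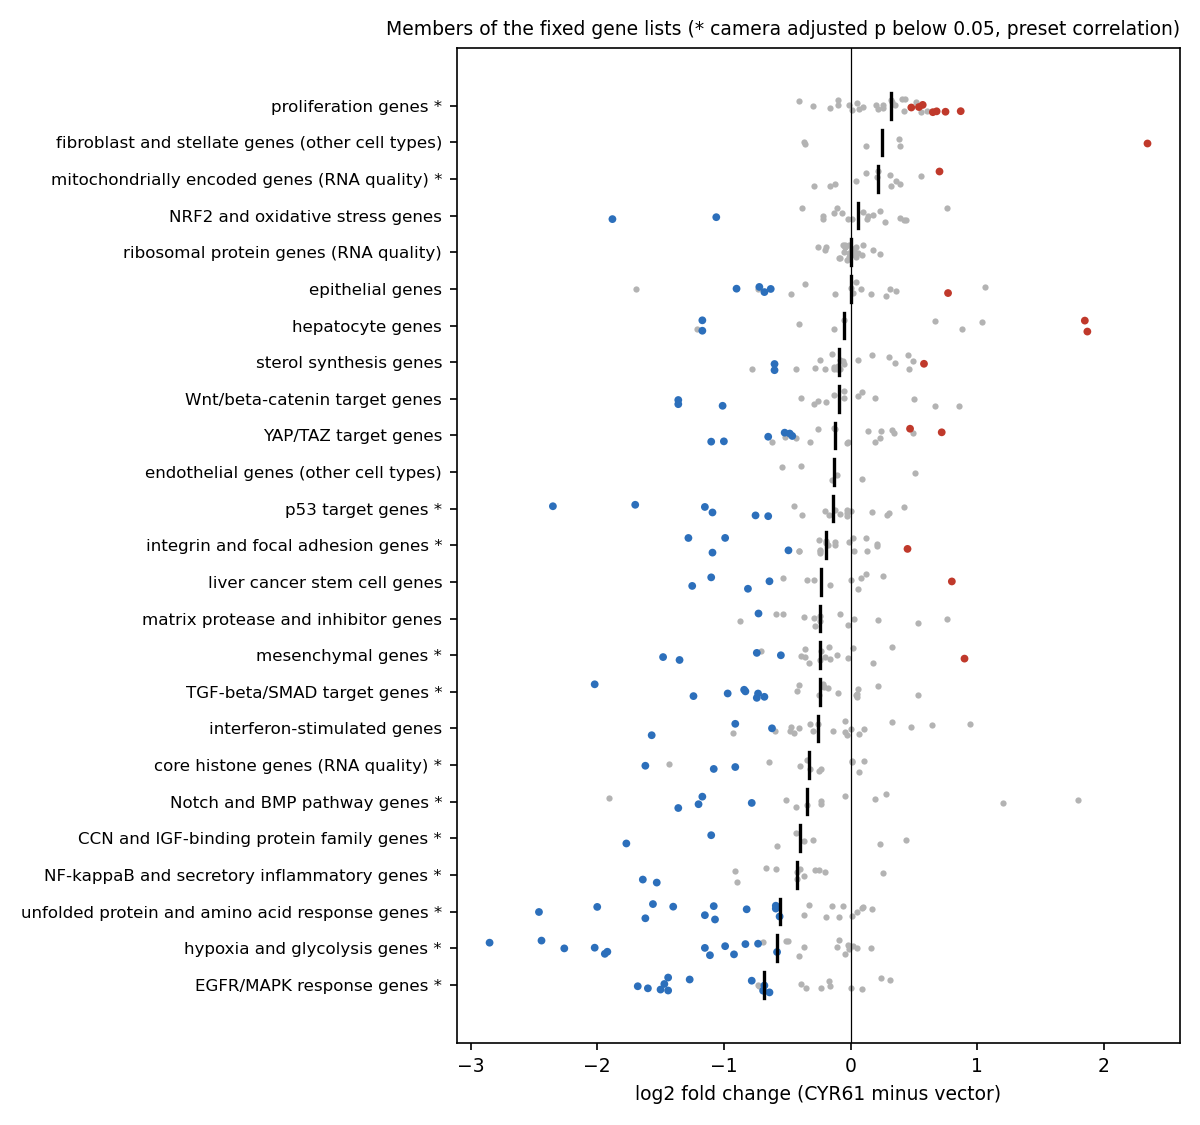
Log2 fold change (CYR61 minus vector) of each tested member of the 25 tested lists, with called members in red (higher) or blue (lower), other members in grey and the list median as a black bar; vertical jitter carries no meaning. An asterisk marks lists called by camera with the preset correlation, and medians run from -0.68 for EGFR/MAPK response genes to 0.32 for proliferation genes.

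Adhesion and matrix genes were lower for some members. Of 20 mesenchymal genes, 4 fell and 1 rose, as over the list alone, with a median log2 fold change of -0.24. FN1, encoding fibronectin, fell from 79.4 ± 4.15 to 28.5 ± 0.15 CPM (-1.48, edgeR adjusted p = 0.000191), and SNAI2, a repressor of epithelial genes, from 14 ± 0.298 to 5.53 ± 0.778 CPM (-1.35). COL5A1 (-0.55) and LOX fell and COL6A2 (0.90) rose. By camera the adjusted p was 0.0119, and adjusted p = 0.413 with an estimated correlation; it was 0.0504 without vector 1, 0.101 without CYR61 1 and 0.0509 with the GC trend removed. Of 23 integrin and focal adhesion genes, 4 fell (6 adjusted over the list alone) and 1, CAV1 (0.45, edgeR adjusted p = 0.0444), rose. The CAV1 call was lost with the replicate block and when any of the 4 libraries was left out. ITGA2 (-1.28), ITGB4 (-1.09), ITGA5 (-0.99) and ITGA3 (-0.49) were lower. For this list the camera adjusted p was 0.0486, and adjusted p = 0.413 with an estimated correlation; it was 0.059 to 0.192 when any of the 4 libraries was left out, 0.0507 with RLE size factors and 0.0948 without a filter. Of 19 epithelial genes, 4 fell and 1 rose (6 and 4 adjusted over the list alone), and the list was not called (camera adjusted p = 0.524). CLDN1 (-0.90), CLDN7 (-0.72) and ELF3 (-0.68) fell, and the splicing factor gene ESRP2 (0.77) rose. CLDN7 overlaps ENSG00000262302, and the sum over both changed by -0.72. Of 15 matrix protease and inhibitor genes, PLAUR (-0.73) fell, with 4 lower adjusted over the list alone (camera adjusted p = 0.094, but 0.0282 with the stricter filter and 0.0439 with limma-voom). Calls lost without vector 1 included CLDN7 (log2 fold change -0.62), ELF3 (-0.55), PLAUR (-0.60), COL5A1 (-0.53) and ITGA3 (-0.44). Those lost without vector 2 included COL5A1 (-0.56), ITGA3 (-0.54) and COL6A2 (0.80). Those lost without CYR61 1 included COL5A1 (-0.47) and ITGA3 (-0.38). ITGA3 was also not called with RLE size factors (edgeR adjusted p = 0.0546).

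IGFBP1, a secreted binding protein for insulin-like growth factors, fell from 57.8 ± 5.39 to 17 ± 1.17 CPM (log2 fold change -1.77, edgeR adjusted p = 0.000176). With IGFBP3 it made up the 2 lower of 8 CCN and IGF-binding protein genes (6 lower and 1 higher adjusted over the list alone, median -0.40). The camera adjusted p was 0.0306, and adjusted p = 0.526 with an estimated correlation; it was 0.0764 without vector 1 and 0.148 without CYR61 1, and fry gave 0.079. Of 15 Notch and BMP pathway genes, 4 fell (6 lower and 2 higher adjusted over the list alone). These 4 were the Notch targets HES1 (-1.36) and HEY1 (-1.17), the BMP antagonist gene NOG (-1.20) and the ligand gene JAG1 (-0.78). The 2 higher over the list alone were BMP4 (1.80) and another Notch target, HEY2 (1.20). Over the 15 members, 11 log2 fold changes were below 0 and 4 above. By camera the adjusted p was 0.0486, and adjusted p = 0.526 with an estimated correlation; it was 0.122 without vector 1, 0.233 without CYR61 1, 0.0625 without a filter and 0.0516 with the GC trend removed, and fry gave 0.1. Lower members numbered 3 without vector 1, 3 without CYR61 1 and 7 without CYR61 2. NOG was not called without CYR61 1 (edgeR adjusted p = 0.077) and JAG1 was not called without vector 1 (0.0558).

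Several other lists held single changed genes and were not called in the planned test, though 3 of them were called under alternatives. Among 11 hepatocyte genes, FGA and FGB rose and CEBPA (-1.17) and RBP4 (-1.17) fell, as over the list alone (camera adjusted p = 0.627). That list's median was -0.05 and its mean 0.20. Among 16 Wnt/beta-catenin target genes, 3 fell, NOTUM (-1.36), NKD2 (-1.36) and PORCN (-1.01), as over the list alone, where 1 rose (camera adjusted p = 0.524). Among 14 liver cancer stem cell genes, NES (-1.25), SOX9 (-1.10), KLF4 (-0.81) and ANPEP fell and ALDH1A3 (0.80) rose, with 5 lower adjusted over the list alone (camera adjusted p = 0.123). With the stricter filter, camera called the Wnt (0.0282) and stem cell (0.036) lists. Among 20 NRF2 and oxidative stress genes, the cystine transporter gene SLC7A11 (-1.88) and ABCC3 (-1.06) fell, as over the list alone (camera adjusted p = 0.594). The median of that list was 0.06 and its mean -0.05, and camera gave the direction as up and fry as down. Among 23 interferon-stimulated genes, ISG20 (-1.57), IRF9 (-0.91) and ISG15 (-0.62) fell, with 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0675). That list was called lower with the stricter filter (0.0132), with limma-voom (0.0433), by fry (0.0459) and with the GC trend removed (0.0295). IRF9 overlaps ENSG00000259529, and the sum over both changed by -0.21, so the fall of IRF9 is uncertain. Among 24 sterol synthesis genes, 2 fell, among them SCD (-0.60), and HMGCS1 (0.58) rose, with 4 lower and 4 higher adjusted over the list alone (camera adjusted p = 0.755). Without vector 1, RBP4 (edgeR adjusted p = 0.0506), IRF9 (0.217), ISG15 (0.183) and HMGCS1 (0.188) were not called. Without CYR61 1, IRF9 (0.0518), ISG15 (0.0917) and HMGCS1 (0.155) were not called, and ALDH1A3 was not called without vector 2 (0.163). IRF9 was not called by DESeq2 (0.0619), nor HMGCS1 with library size alone (0.0617).

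**Figure D3:**
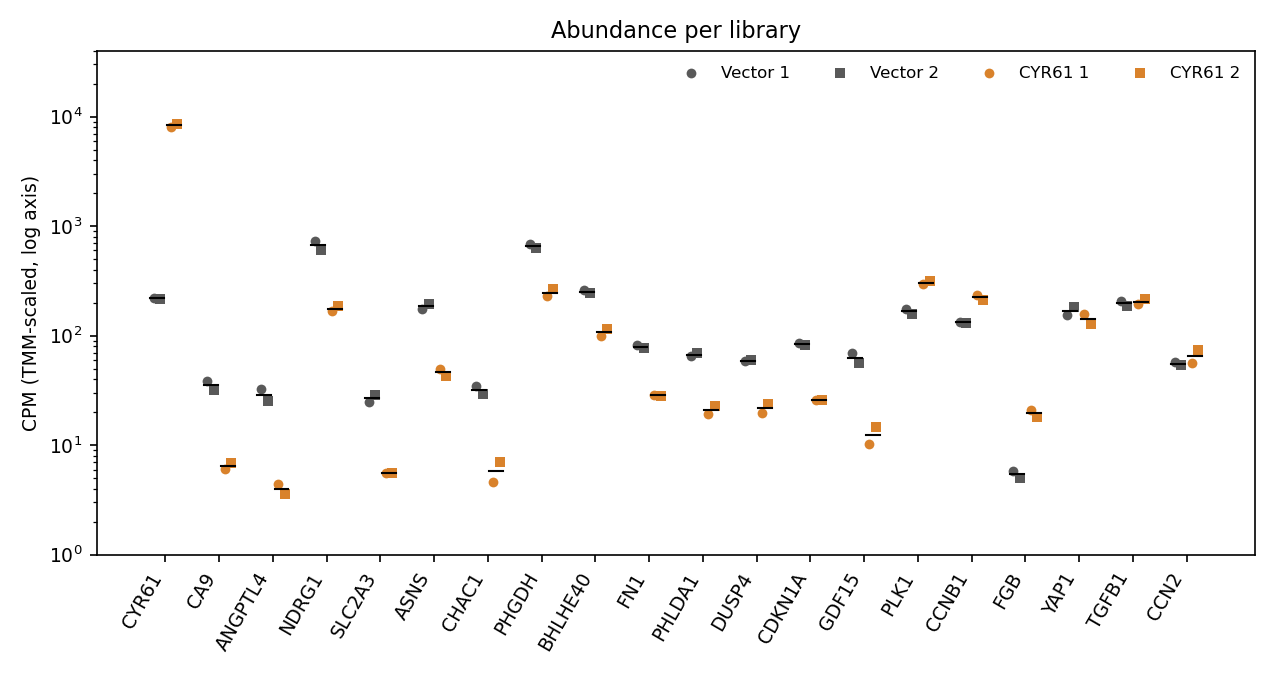
TMM-scaled CPM of 20 genes in each library on a log axis, with vector libraries in grey, CYR61 libraries in orange, circles for replicate 1, squares for replicate 2 and black bars for group means. YAP1, TGFB1 and CCN2 were not called, and each other gene shown was called.

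Markers of other cell types and RNA quality genes were measured in the same comparison. Of 17 leukocyte genes, 2 were tested, too few for a list test, and ITGB2 (-0.92) was lower. ITGB2 was not called without vector 1 (edgeR adjusted p = 0.243), without CYR61 1 (0.091), by limma-voom (0.0523) or with library size alone (0.0611). None of 6 endothelial genes was called by edgeR (camera adjusted p = 0.549), with 1 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. The member of smallest p was ESAM (-0.39, edgeR adjusted p = 0.107; 0.0147 with the GC trend removed). Of 6 fibroblast and stellate genes, DCN rose (camera adjusted p = 0.307), and the list was called without vector 1 (0.0317) and without CYR61 1 (0.0296). The list of 14 core histone genes had a median of -0.33, with 4 members above 0 and 11 not called, and 3 lower members (5 adjusted over the list alone), among them HIST2H2AA3 (-1.62) and H2AC6 (-1.08). For this list the camera adjusted p was 0.00165, and adjusted p = 0.326 with an estimated correlation. HIST2H2AA3 has a near-identical copy and is uncertain. The 13 mitochondrially encoded genes had a median of 0.22, and MT-ND1 (0.70) was higher, with 2 higher adjusted over the list alone. The camera adjusted p was 0.043, and adjusted p = 0.586 with an estimated correlation; it was 0.111 without vector 1, 0.162 without CYR61 1 and 0.0892 with the GC trend removed, and fry gave 0.201. None of 28 ribosomal protein genes was called by edgeR, with a median of 0.00 (camera adjusted p = 0.767), and RPL3 had the smallest p (-0.26, edgeR adjusted p = 0.206). At an unadjusted p under 0.05 there was 1 such gene, and DESeq2 and limma-voom called 0. MT-CO1, the gene with most reads, was at 13300 ± 313 and 11900 ± 45.9 CPM (-0.16, edgeR adjusted p = 0.388).

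Over the 25 lists, 13 were called by camera with the preset correlation and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. For EGFR/MAPK response genes the estimate was 0.015 against the preset 0.01, yet the unadjusted camera p went from 5.31e-09 to 0.0306. For hypoxia and glycolysis genes the estimate was 0.252. Camera with an estimated correlation also uses the few residual degrees of freedom of 4 libraries. Loss of a call there does not show that correlation between genes explains the list. Fry called 9, of which 8 were among the 13. The shifts of the histone list (-0.33) and of the mitochondrial list (0.22) went with the same group contrast as the hypoxia, amino acid, EGFR/MAPK and proliferation lists.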

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

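The CYR61 level kept its direction and its call under each alternative, with log2 fold changes from 5.20 to 5.31. No gene called in the reported comparison changed sign under an alternative in which it was tested. The 811 calls (232 higher, 579 lower) became 1677 without a filter (648 and 1029), 115 against a minimum fold of 1.5 (10 and 105), and DESeq2 called 377 higher. With 1 library left out the calls ranged from 481 to 1331 (104 to 538 higher, 377 to 793 lower). In those fits the lone library is assumed to vary like the other group. Alternatives chosen after seeing the data gave 3621 calls with the GC trend removed (2092 higher, 1529 lower) and 2332 with the GC trend removed and the replicate block (1309 and 1023). Of the title's pathway genes called with the GC trend removed, SMAD2 (edgeR adjusted p = 0.0189) and TEAD4 (0.0213) stayed called with the block added. The cause of these changes was not tested.

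The replicate block gave 391 calls (53 higher, 338 lower). Same-numbered libraries deviated from their group means in opposite directions (correlation across genes -0.72), so the numbers do not pair the libraries in this deviation. Whether cultures of the same number were grown or harvested together is not given in the labels. Calls ended with the block included IRF9 (edgeR adjusted p = 0.0764), JAG1 (0.0905), PLAUR (0.0678), CLDN7 (0.1), ELF3 (0.0719), NT5E (0.145), ISG15 (0.115) and SCD (0.0987). They also included COL5A1 (0.165), ITGA3 (0.253), HMGCS1 (0.164), KIF20A (0.0782), AURKA (0.0665), FJX1 (0.0992), ALDH1A3 (0.0804) and KCND3 (0.0754). By camera the integrin (0.122), Notch and BMP (0.0644) and mitochondrial (0.0796) lists were not called, and the fibroblast list was (0.0497). Crossed numbers as a block, chosen after seeing the data, gave 5624 calls (2748 higher, 2876 lower).

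Of the alternative values of named genes, 1684 kept direction and side of the threshold, 114 lost the call, 18 gained it and 3 turned in sign. Those 3 were TGFBR1 (0.03) and TGFB1 (-0.03) without vector 2 and TGFB1 (-0.02) without CYR61 2, with no call either way; with 1 library left out TGFBR1 ranged from -0.21 to 0.03 and TGFB1 from -0.03 to 0.14. The 13 called lists fell to 0 with an estimated correlation. Set tests with DESeq2 or a minimum fold were not run, and the alternatives planned for FPKM values were not applicable. Lists that turned in direction were not called either way. By camera adjusted p these were NRF2 (0.989 with the replicate block, 0.937 without vector 2), sterol synthesis (0.989 with the block, 0.938 without vector 1) and ribosomal protein genes (0.59 without vector 2, 0.715 without CYR61 2). With 1 library left out these lists ranged from 0.503 to 0.937, from 0.794 to 0.979 and from 0.2 to 0.715. By fry they were NRF2 (0.688) and ribosomal protein genes (0.95). With 2 cultures per group, the self-test recovered 30% of genes changed 1.5-fold, so smaller changes are poorly covered. It recovered 6% where a further GC trend was added and left in, which has more spread than the reported fit.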

Other observations

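The gene families below were picked by symbol after the fold changes had been seen, so their tests are descriptive, and all tests of explanations that follow were also chosen after the result was seen. The heat shock pattern was narrowed after its first test, which had counted HSPG2, a matrix proteoglycan; both versions are given, and 14 family patterns were tested in all. Of 68 heat shock and DnaJ genes, 10 rose and 2 fell (camera adjusted p = 0.00601). With chaperone symbols alone, 10 of 65 rose and 1 fell (camera adjusted p = 0.00236). The higher members included the HSP70 genes HSPA8, from 676 to 1460 CPM (log2 fold change 1.11), HSPA1B (0.96) and HSPA1A (0.84), the last 2 near-identical copies and uncertain, and DNAJA1 (0.99). HSPE1-MOB4, a read-through model, is also counted among them. Of 26 NOP, UTP and RRP ribosome assembly genes, 5 rose, among them NOP2 (0.76) and UTP20 (0.74), and 0 fell (camera adjusted p = 3.11e-07). Of 48 proteasome genes 4 rose (camera adjusted p = 1.72e-05), of 20 tubulin genes 5 rose (0.0172), and of 7 chaperonin genes CCT2 rose (0.00601), with 0 lower in each. With an estimated correlation none of these families was called by camera (adjusted p = 0.377 with an estimated correlation, and 0.552 for tubulin genes). With the GC trend removed, the counts higher and lower were 24 and 6 for the 68 heat shock genes, 21 and 0 for ribosome assembly, 28 and 3 for proteasome, 10 and 2 for tubulin and 6 and 0 for chaperonin genes.

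In the other direction, 7 of 18 cytosolic aminoacyl-tRNA synthetase genes fell, including CARS1 (-1.54), GARS1 (-1.18), AARS1 (-1.05) and MARS1 (-0.99), while KARS1 (0.48) and RARS1 (0.71) rose (camera adjusted p = 0.00803). Of 17 amino acid carrier genes, 8 fell, among them SLC7A11 (-1.88) and SLC1A4 (-1.13), and 0 rose (camera adjusted p = 0.0333). Of 24 collagen genes 7 fell and 1 rose (camera adjusted p = 0.0235), of 13 keratin genes 2 fell (0.0172), and of 48 histone genes 4 fell (0.00236). The dual-specificity phosphatase (0.123), ZNF (0.16) and HLA (0.441) families were not called by camera. With an estimated correlation none of these was called either (adjusted p from 0.377 to 0.562). No family changed direction with RLE, upper quartile or library size scaling. With the GC trend removed, 11 synthetase genes were lower and 4 higher, 10 amino acid carrier genes lower and 4 higher, and the collagen (0.0979) and keratin (0.0555) families were not called.

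Of the hypoxia, amino acid response and EGFR/MAPK lists, 13 of 27, 12 of 23 and 11 of 22 tested members fell, with medians of -0.58, -0.56 and -0.68 over all tested members. By camera none of these lists was called with an estimated correlation (adjusted p = 0.413, 0.326 and 0.326). Over the 36 called members, which were selected for their fall, the median was -1.21 (SD 0.61). With the GC trend removed, the median of these called members was -1.14, and over all tested members the 3 medians were -0.53, -0.49 and -0.59. A bias following that trend can therefore account for a small part of the fall at most. The median of all tested genes also moved, from -0.006 to 0.033, so the shift was not particular to these lists. Among genes of at least 5 CPM, the median log2 fold change was 0.07 at 31.3% to 42.1% GC and -0.06 at 56.8% to 74.7% GC. The 36 members remained called, but so did each of the 811 called genes, so that count cannot test GC bias for these lists. Reads taken by the introduced CYR61 could change other genes by -0.012 at most on the log2 scale. Culture state at harvest, such as density or medium exhaustion, cannot be told apart from CYR61 expression: it is not recorded and would separate the groups in the same way, and proliferation genes had a median of 0.32 (SD 0.32). An effect of CYR61 itself, or of the making of a single stable population, stays open as an untested explanation.

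Libraries of opposite replicate number deviated together, with a correlation across genes of 0.72 between vector 2 minus vector 1 and CYR61 1 minus CYR61 2. GC content is a candidate explanation, since the absolute rho with GC content was at least 0.73 in both groups and removing the trend lowered the correlation to 0.39, which leaves part of it open. Transcript length had an absolute rho of at most 0.27, which speaks against it as the cause. Depth goes with the pattern, since both differences were the library of higher total minus that of lower total. The totals were 21588822 (vector 2) against 19118548 (vector 1) and 21388465 (CYR61 1) against 16186988 (CYR61 2) estimated counts. The correlation was 0.7 after thinning each library to the total of the smallest, so counting error at unequal depth explains little of it. Thinning cannot remove a bias that goes with depth, so depth stays open. No biological explanation was tested.

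Besides CYR61, 6 identifiers changed by at least 5 on the log2 scale, namely FAM220A, ENSG00000262526, ENSG00000269693, HSPE1-MOB4, ENSG00000285901 and a second identifier of HERC3. Division of reads between overlapping models may explain these changes, but the summed CPM of the locus could have shown it at 1 of the 6 loci. At FAM220A the sum would have changed by -1.29 on the log2 scale with unchanged partners and changed by -0.10. At the other loci the identifier held 0.372% to 23.1% of the sum, too little to decide, and some sums changed more than division of reads alone would give, by -0.70 at HERC3 and by 0.49 at HSPE1-MOB4. A change in transcript form was not tested, and an effect of CYR61 expression stays open.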
